A study of Mus musculus with 35 samples.

How the data were processed

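The scanner files hold spot intensities of a 2-colour mouse array that, per the file headers, were extracted with Feature Extraction 11.0.1.1: Cy5 carries lung RNA and Cy3 a universal mouse reference RNA, in the same orientation on all 35 arrays, from 200 ng of RNA each. The series values are, as deposited by the authors, log2 ratios of Cy5 to Cy3. The authors' normalization is not given in the sources used here; the deposited values correlated at 0.994 to 1.00 (median 0.997) with loess-normalized log2 ratios made without background subtraction, with a median slope of 0.994. The scanner intensities were used in place of those values. Median intensities were background-corrected with normexp (offset 50) and normalized within arrays with loess in limma 3.58.1 under R 4.3.3, with the data.table package in version 1.17.8. Each array held 59305 spots besides 3671 control spots, for 55681 probes, of which 27235 matched a gene symbol through the accessions in the RefSeq annotation of GRCm38.p6 and 28446 did not. Spots marked as non-uniform or as population outliers in either channel were left out, which left 1403 probe values missing, and 0 Cy5 values were saturated. A probe was tested if it lay well above background in Cy5 on at least 3 of the 5 arrays of at least 1 group, so that 34326 probes remained (20228 with a symbol). The brightest probe stood for each gene; 25534 features were tested, 15621 of them genes with a symbol, 3885 with more than 1 tested probe, and 653 features had a missing value. The 7 slides, scanned on 6 days, held 8, 4, 8, 6, 3, 3 and 3 arrays, and controls lay on 4 of them.

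Linear models over all 35 arrays with moderated variance (limma eBayes) gave the changes, SE and p-values of single genes, and p-values were adjusted within each of 18 comparisons by the Benjamini-Hochberg method; a feature was called at an adjusted p under 0.05. These comparisons were 6 of a treated group with control, 3 between doses, 6 between materials at matched dose and 3 of dose effects. Gene lists, 52 in number, were tested with camera from limma at a correlation of 0.01, and again with an estimated correlation, with adjusted p over the 52 lists of a comparison. List scores, the mean log2 ratio of the members on each array, were compared with exact 2-sided permutation tests over the 252 splits of 10 arrays, adjusted over 312 tests for treated groups. Intervals are 95% and belong to these scores; list means given in the report are differences of the scores, and those under alternatives and for dose effects average the changes of the members, which can differ where a member lacked a value. Genes named in the report come from a fixed rule: the 10 largest changes in each direction with an adjusted p under 0.05 and all 5 arrays on the same side of the control mean, up to 4 members of each list described, the 5 largest in each direction for doses and materials, and 16 genes named in any case, of which Cxcl2 was not tested. Alternatives were run on 998 of the gene results so named, and the report covers a part of them. The comparisons, lists, rule, settings and alternatives were chosen before the data were examined, and 4 alternatives were added afterwards. Alternatives changed the background correction, the values used, the normalization, the filter, the probe summary, the marked spots, the handling of slides, the arrays in the fit, the variance model, array weights, the fold threshold, the list test and the controls, and left out each array in turn.

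The procedure was tested on simulated data, with changes set in NRCWE-043 at 18 µg against control, 50 genes for each change. Each gene had its residual spread pooled over all 7 groups. The noise was independent between arrays, so slides and outlying arrays were not simulated and recovery in the real comparison can be lower. The procedure recovered 50% of changes of 0.5 on the log2 scale, 96% of 1, 100% of 1.5 and 98% of 2. It made 9 false calls, and 0 calls in an unchanged comparison. A list shifted by -0.5 was called lower, and 0 others were called.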

Results

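Lung RNA from 35 arrays was compared in 7 groups of 5: controls that received 0 µg, and female C57BL/6 mice 24 h after a single instillation into the trachea of 18 or 54 µg per animal of NRCWE-043, NRCWE-044 or NRCWE-045 in 40 µl. The series title calls these code-named materials nanomaterials and states the aim of ranking how strongly they perturb pathways in the lung. What the controls received besides 0 µg is not stated. The labels also do not state that the arrays of a group are separate mice, so the p-values measure the spread between these samples, of which a part can be technical. Values are log2 ratios of lung RNA to a universal mouse reference RNA on 2-colour arrays, and changes are differences of group means on that scale. In the lung (Cy5) channel 42.8 to 69.3% of probes lay well above background, at median signals of 85.5 to 345.5. Within groups this share ran from 44.1 to 59.3% in controls, 51.6 to 59.0% and 44.6 to 55.3% for NRCWE-043 at 18 and 54 µg, 47.8 to 68.5% and 44.1 to 69.3% for NRCWE-044, and 42.8 to 54.2% and 42.9 to 58.5% for NRCWE-045. The number of arrays, 5 per group, limits the precision.

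The comparisons of each dose with the controls asked how far lung transcripts differed from control at 24 h with each material, and NRCWE-043 at 54 µg gave the largest count. The acute phase gene Saa3, a serum amyloid A that inflamed tissue makes, rose by 6.80 (SE 0.99, adjusted p = 5.1e-05) on the log2 scale, from -2.57 ± 2.20 (SD, n = 5) in controls to 4.22 ± 0.79 (SD, n = 5). Saa1 rose by 3.96 (SE 0.59, adjusted p = 5.9e-05), and Orm2, which encodes a plasma glycoprotein of the same response, by 3.12. 10 of 15 acute phase genes rose (11 adjusted over the list alone). Among the CC chemokines, which draw leukocytes, 9 of 14 rose (10 adjusted over the list alone), among them the monocyte attractants Ccl7, by 3.21 (SE 0.41, adjusted p = 9.4e-06), and Ccl2, by 2.73 (SE 0.39, adjusted p = 4.3e-05). The interferon-induced chemokine Cxcl10 rose by 3.18, the metalloproteinase inhibitor Timp1 by 3.62, the cytokines Il1b and Il6 by 1.74 and 1.18, and Lcn2, which binds bacterial iron carriers, by 1.41. Hmox1, the enzyme that breaks down heme, rose by 2.71 (SE 0.32, adjusted p = 4.1e-06). Each of these changes was seen in all 5 treated arrays relative to the control mean. A dimmer probe of Hmox1 rose by 0.81. Cxcl1, Cxcl5 and Mt2 did not pass the test, at 0.90 (adjusted p = 0.16), 1.14 (adjusted p = 0.23) and 0.90 (adjusted p = 0.14), nor did Sftpc, at -0.56 (adjusted p = 0.11), or Cyp1a1, at -0.57 (adjusted p = 0.14). Cyp1a1 was at -0.19 without control replicate 30, which stood at 2.31. It was at -0.93 without control replicates 7 and 29, when it was called (adjusted p = 0.015), but that fit kept replicate 30. Cyp1a1 lay well above background in 1 of the 5 treated arrays, so its values there were mostly near background.

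Members of further lists were called with NRCWE-043 at 54 µg, while 0 of the 27 lists called held with an estimated correlation. 13 of 23 interferon-response genes rose (22 adjusted over the list alone), such as Isg15 by 1.98, Ifit1 by 1.20 and the transcription factor Irf7 by 1.16. 10 of 20 genes of cholesterol synthesis rose (16 adjusted over the list alone), with Idi1 of the mevalonate pathway at 0.80. 7 of 16 complement genes rose (8 adjusted over the list alone), led by C3 at 1.57 and Cfb at 1.19. 9 of 19 genes of the unfolded protein response rose and 1 fell, the chaperone Sdf2l1 rising by 1.36. Of 16 markers of monocytes and interstitial macrophages 8 rose and 3 fell, and of 20 neutrophil markers 7 rose and 2 fell. The receptors Ccr2, at 1.16, and Cxcr2, at 1.45, rose, while the integrin Itgam, at -1.34, and the growth factor receptor Csf3r, at -0.90, fell. The fall of Itgam was not called with the mean over its probes (adjusted p = 0.69). 4 of 9 club cell markers fell, among them Scgb1a1, the secretory protein of that cell, at -0.83 (SE 0.20, adjusted p = 0.0056), and Cbr2, at -0.87. Scgb1a1 was not called with median centring, the Cy5 channel alone or scale normalization (adjusted p = 0.76, 0.87 and 0.68), nor was Cbr2 (adjusted p = 0.79, 0.30 and 0.14). Hmox1 belongs to the NRF2 target list, which itself was not called (mean 0.10, adjusted p = 0.55).

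In the competitive list test the mean log2 change was 1.71 for the acute phase (95% interval 1.16 to 2.25, adjusted p = 8.2e-10, and adjusted p = 0.082 with an estimated correlation) and 1.41 for CC chemokines (0.92 to 1.90, adjusted p = 1.9e-09, and adjusted p = 0.082 with an estimated correlation). It was 0.80 for interferon response (0.44 to 1.17, adjusted p = 1.5e-13, and adjusted p = 0.13 with an estimated correlation) and 0.47 for cholesterol (0.31 to 0.63, adjusted p = 3.3e-10, and adjusted p = 0.082 with an estimated correlation). Complement gave adjusted p = 2.3e-05, and adjusted p = 0.13 with an estimated correlation. The unfolded protein response gave adjusted p = 4.4e-04, and adjusted p = 0.15 with an estimated correlation. Club cell markers gave adjusted p = 7.8e-04, and adjusted p = 0.25 with an estimated correlation. Monocyte markers gave adjusted p = 0.001, and adjusted p = 0.25 with an estimated correlation, and neutrophil markers adjusted p = 0.0025, and adjusted p = 0.34 with an estimated correlation. All 5 treated arrays lay on that side of the control mean for each of these lists. Exact 2-sided permutation tests of the list scores gave p = 0.0079 for acute phase, CC chemokines and cholesterol, the smallest that 252 splits allow, and 0.063 after adjustment over 312 tests. For interferon response the exact test gave p = 0.016, adjusted 0.093. Within the slides that hold both groups the difference ran from 1.58 to 2.10 for acute phase, 1.34 to 1.88 for CC chemokines and 0.26 to 0.99 for interferon response. In all, 20 lists were called higher and 7 lower, and 0 with an estimated correlation (limma camera). Endothelial markers, 1 of the 7, had a mean of -0.21 (1 of 21 fell, 1 adjusted over the list alone; adjusted p = 0.041, and adjusted p = 0.71 with an estimated correlation), which turned to 0.04 with median centring and 0.08 with scale normalization.

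The largest falls with NRCWE-043 at 54 µg included the class I histocompatibility gene H2-Q4, at -2.31 (SE 0.32, adjusted p = 3.2e-05), and the sulfate transporter Slc26a1, at -2.06. BC061237 was above background in 0 of 5 treated and 4 of 5 control arrays, so its fold is a bound, at least 3.16-fold lower. A second probe of that gene was at -0.59. H2-Q4, Slc26a1 and Hmox1 belong to 830 features, 151 higher and 679 lower and 375 with a gene symbol, that set the 10 NRCWE-043 arrays apart from both other materials at both doses. On a score where the other materials average 0 and NRCWE-043 averages 1, the NRCWE-043 arrays lay at 0.918 to 1.06, the arrays of the other materials at -0.224 to 0.277, and 4 controls at -0.259 to 0.289. The features were chosen on the treated arrays, whose separation therefore follows from the choice. No control entered that choice. Control replicate 7 lay at 0.878. Its Hmox1 log2 ratio was -1.43, against -3.64 in the other controls, -0.73 in NRCWE-043 arrays and -3.54 in the other materials. Limma called 2606 of 25534 features, 1360 higher and 1246 lower, with 5862 at an unadjusted p under 0.05; 1180 also changed at least 1.5-fold. Without control replicates 7 and 29, an alternative chosen after seeing the data, 3197 were called, and without control replicate 30 alone 1441. Median centring in place of loess moved the median of all genes by 0.11 and gave 524 calls, 67.0% of them higher against 52.2%.

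With NRCWE-044 at 54 µg genes of many of the same groups were called. Saa3 rose by 7.03 (SE 0.99, adjusted p = 5.0e-05), from -2.57 ± 2.20 (SD, n = 5) to 4.46 ± 1.01 (SD, n = 5), and Saa1 by 3.97. 10 of 15 acute phase genes rose (11 adjusted over the list alone). 10 of 14 CC chemokines rose (11 adjusted over the list alone), with Ccl7 at 3.22 (SE 0.41, adjusted p = 2.2e-05), Ccl2 at 2.85, Ccl8 at 2.69 and the eosinophil attractant Ccl24 at 4.18 (SE 0.66, adjusted p = 1.7e-04). The neutrophil attractant Cxcl5 rose by 3.11 (SE 0.57, adjusted p = 9.1e-04), and Cxcl10 by 3.25. Timp1 rose by 3.68, the metal-binding Mt2 by 1.60, Lcn2 by 1.72 and Il1b by 1.39. Il6 and Cxcl1 rose by 0.98 and 1.38, and lost the call without replicate 4 or 34 or control replicate 30 (Il6, adjusted p = 0.065 to 0.075) and without replicate 24 or 34 or control replicate 7, 15 or 30 (Cxcl1, adjusted p = 0.073 to 0.12). 19 of 23 interferon-response genes rose (22 adjusted over the list alone), such as Irf7 by 1.57 and Oasl2 by 1.46. 7 of 11 genes of alternative macrophage activation rose (9 adjusted over the list alone), with Arg1, the enzyme that hydrolyses arginine, at 2.48. The score of this list was 4.28, 3.79 and 3.79 on replicates 4, 18 and 34, which also carried markers of adipose tissue (5.20, 0.37 and 3.81) or heart muscle (2.15, 2.35 and 0.95). It was 2.99 and 3.06 on replicates 24 and 31 (adipose 0.15 and 0.54, heart -0.05 and -0.09). In controls it was 1.68 to 2.69, highest on replicates 2 and 29, whose heart scores were 2.64 and 2.90. 8 of 20 cholesterol genes (15 adjusted over the list alone) and 9 of 19 genes of the unfolded protein response rose, while 1 of the latter fell. The chaperones Sdf2l1 and Calr rose by 1.85 and 1.13. The anion exchanger Slc26a4 rose by 3.94. The glutathione transferase Gsta2, at -1.84, fell. Hmox1, at -0.29 (adjusted p = 0.7), Scgb1a1, at -0.12 (adjusted p = 0.83), Sftpc, at -0.04 (adjusted p = 0.96), and Cyp1a1, at -0.39 (adjusted p = 0.41), did not pass the test. Without control replicate 30 Cyp1a1 was at -0.01, and without control replicate 7 Hmox1 was at 0.15. Cyp1a1 lay well above background in 2 of the 5 treated arrays.

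The mean log2 change was 1.07 for interferon response (95% interval 0.70 to 1.44, adjusted p = 4.0e-27, and adjusted p = 0.017 with an estimated correlation), 1.76 for acute phase (1.21 to 2.31, adjusted p = 1.0e-13, and adjusted p = 0.017 with an estimated correlation) and 1.65 for CC chemokines (1.16 to 2.14, adjusted p = 1.0e-13, and adjusted p = 0.017 with an estimated correlation). Cholesterol, at 0.42, gave adjusted p = 2.1e-10, and adjusted p = 0.027 with an estimated correlation. Alternative macrophage activation, at 1.44, gave adjusted p = 6.5e-10, and adjusted p = 0.017 with an estimated correlation. The unfolded protein response, at 0.49, gave adjusted p = 2.4e-08, and adjusted p = 0.017 with an estimated correlation. Each of these lists lay above the control mean in all 5 arrays, with exact permutation p = 0.0079 (2-sided, 0.063 after adjustment over 312 tests). Within slides that hold both groups the difference ran from 1.54 to 1.99 for acute phase, 1.42 to 2.12 for CC chemokines and 0.84 to 1.23 for interferon response. Camera called 20 lists higher and 6 lower, of which 11 held with an estimated correlation. Among them the circadian clock list fell (7 of 16 members lower, 1 higher, mean -0.49, adjusted p = 0.0018, and adjusted p = 0.045 with an estimated correlation). Dbp, a clock output gene, changed by -2.57 (SE 0.63, adjusted p = 0.011), and the repressor Nr1d1 by -1.70 (SE 0.43, adjusted p = 0.014). The controls themselves spread over 3.66 log2 units on a score of clock phase, from -1.27 to 2.40 (2.53 units and -1.27 to 1.27 without control replicates 7 and 29), and the NRCWE-044 arrays at 54 µg lay at -1.24 to -0.55. Without control replicate 7 neither Dbp (adjusted p = 0.057) nor Nr1d1 (adjusted p = 0.073) was called, and without control replicate 29 Nr1d1 was not (adjusted p = 0.059). Without both arrays Dbp was at -1.01, Nr1d1 at -0.57 and the clock list at -0.26. Limma called 1518 features, 1001 higher and 517 lower (4967 at an unadjusted p under 0.05). The count fell to 752 without replicate 34, 940 without replicate 4, 955 without control replicate 7, and 880 without control replicates 7 and 29. It was 43 with median centring and 746 with the clock score as a covariate, when the median change of the genes called was 0.55 against 0.56 and its median SE 0.17 against 0.14. Higher calls were 65.9% of the total, 53.6% in the deposited values, 53.6% with the Cy5 channel alone and 95.3% with median centring.

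With NRCWE-045 at 54 µg fewer features were called against control, which is not a test of a difference: directly against NRCWE-044 at that dose 0 were called. Saa3 rose by 4.77 (SE 0.99, adjusted p = 0.032), from -2.57 ± 2.20 (SD, n = 5) to 2.19 ± 1.92 (SD, n = 5), with Timp1 at 2.56 (SE 0.57, adjusted p = 0.038), Ccl7 at 2.43 (SE 0.41, adjusted p = 0.014), Ccl2 at 2.00, Cxcl10 at 2.14 and Il1b at 1.30. C3 and Cfb rose by 1.19 and 1.02, the stress-induced transcription factor Atf3 by 0.81, and Ch25h, which makes an oxysterol, by 1.36, in all 5 arrays each. Of the 9 features that fell, 8 had a gene symbol. The pro-apoptotic Bbc3 and Bmf were at -0.53 and -0.72 and the lipoprotein receptor Vldlr at -0.60. Kcnk2, above background in 0 of 5 treated arrays, was at least 1.25-fold lower. 3 of 14 CC chemokines rose (10 adjusted over the list alone; mean 1.09, 95% interval 0.59 to 1.58, adjusted p = 4.1e-12, and adjusted p = 0.038 with an estimated correlation), as did 2 of 20 cholesterol genes (16 adjusted over the list alone; mean 0.38, 0.22 to 0.54, adjusted p = 1.9e-14, and adjusted p = 0.033 with an estimated correlation). 1 of 15 acute phase genes rose (10 adjusted over the list alone; mean 1.08, 0.53 to 1.62, adjusted p = 7.1e-10, and adjusted p = 0.061 with an estimated correlation). Of 23 interferon-response genes 0 rose and 15 did when adjusted over the list alone (mean 0.56, 0.19 to 0.93, adjusted p = 2.8e-15, and adjusted p = 0.089 with an estimated correlation). These 4 lists lay above the control mean in all 5 arrays, with exact permutation p = 0.0079 for cholesterol and 0.016 for the others (2-sided; 0.063 and 0.093 after adjustment over 312 tests). Within slides the difference ran from 0.08 to 2.23 for acute phase, 0.31 to 1.79 for CC chemokines and 0.15 to 0.95 for interferon response. The lowest value of each list came from slide 5, whose only control was replicate 29, an array with raised acute phase genes. No array of NRCWE-043 or NRCWE-044 at 54 µg lay on that slide, so the ranges within slides cannot be compared between materials. Camera called 18 lists higher and 8 lower, 3 of them with an estimated correlation. Saa1 at 2.27 (adjusted p = 0.081), Lcn2 at 1.39 (adjusted p = 0.066), Il6 at 0.87 (adjusted p = 0.16) and Hmox1 at -0.52 (adjusted p = 0.68) did not pass the test; Hmox1 was at -0.07 without control replicate 7.

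For NRCWE-045 at 54 µg limma called 83 features, 74 higher and 9 lower (2396 at an unadjusted p under 0.05), and the count rested on single arrays. Without control replicate 2, 7 or 30 or treated replicate 8 the adjusted p was 0.075 to 0.10 for Saa3 and 0.050 to 0.060 for Ccl7, and without control replicate 15 or treated replicate 14 or 32 it was 0.092 to 0.15 for Saa3. The count was 0 without control replicate 2, 7 or 30 or treated replicate 8, 6 without replicate 14, 13 without replicate 32, 18 without control replicate 15, 33 without replicate 28, 146 without replicate 35 and 221 without control replicate 29. Control replicate 29 had a Saa3 log2 ratio of 1.31, against -3.54 ± 0.44 (SD) in the other controls, and an acute phase score of 2.12, against 0.705 to 1.24. Without control replicates 7 and 29 the count was 100, and without replicates 5, 6, 10 and 23, also chosen after seeing the data, 471 (78.1% higher against 89.2%). With median centring it was 0.

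**Figure D1:**
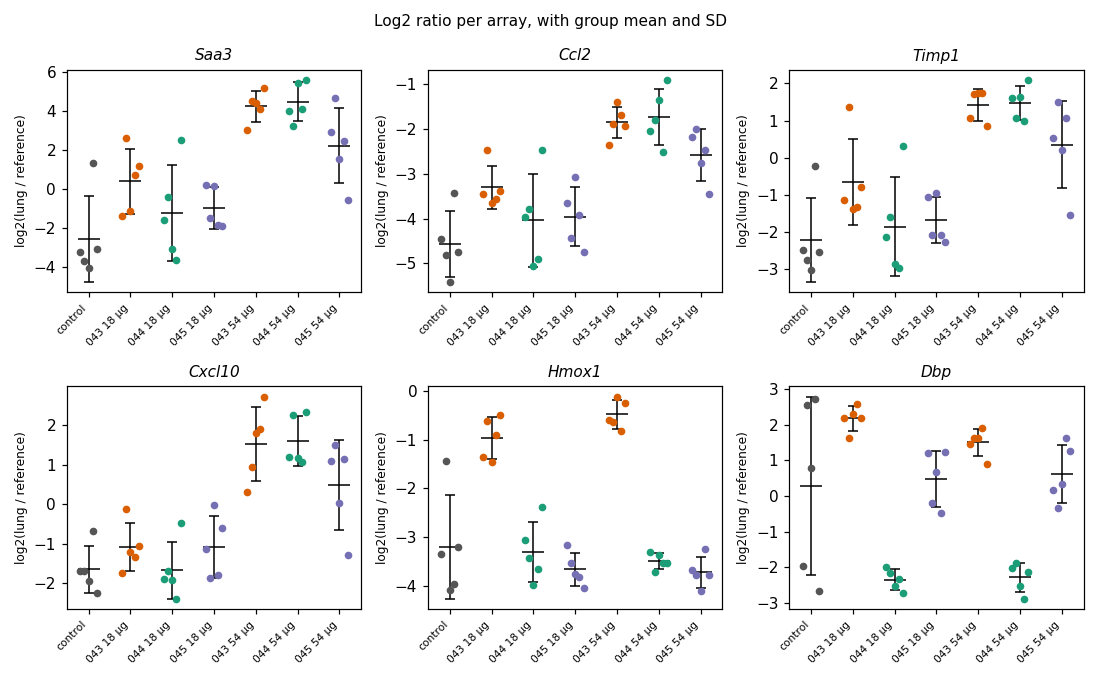
Log2 ratio of lung to reference RNA on each array (points) for 6 genes in the 7 groups, with the group mean and SD (bars). Saa3 averaged 4.22 and 4.46 with NRCWE-043 and NRCWE-044 at 54 µg against -2.57 in controls, where replicate 29 stood at 1.31.

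**Figure D2:**
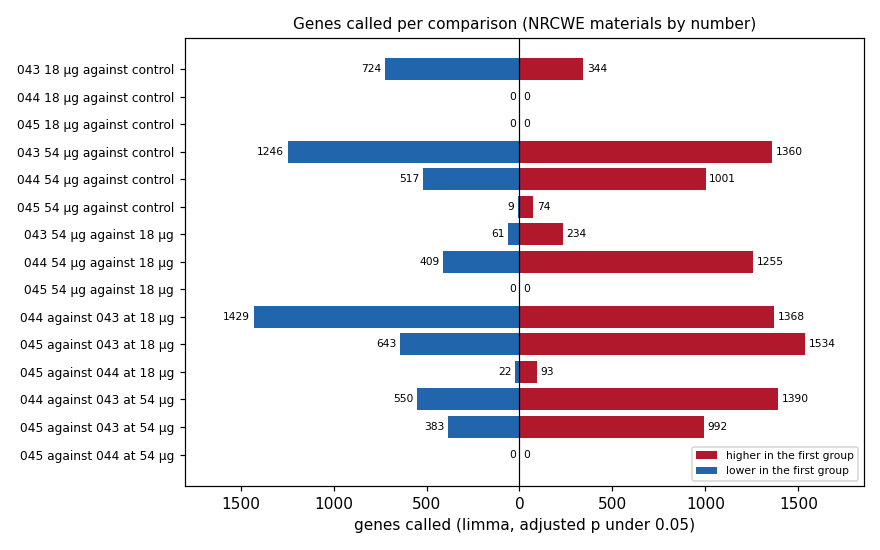
Number of features called by limma at an adjusted p under 0.05 (horizontal axis) in 15 comparisons, higher in the first group to the right and lower to the left. NRCWE-043 at 54 µg against control gave 1360 higher and 1246 lower, and 4 comparisons gave 0.

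Calls at 54 µg overlapped between materials, all measured against the same 5 controls. In all 3 materials 63 features rose, among them Saa3, Ccl2, Ccl7, Cxcl10, Timp1, Il1b, C3 and Cfb, and 6 fell. NRCWE-043 and NRCWE-044 shared 627 higher and 182 lower calls, where independent sets of these sizes share 53.3 and 25.2, and 11 calls had opposite signs. With the controls split between the materials, in 20 ways, the median of shared higher calls was 164.5 (16 to 242). NRCWE-043 shared 66 higher and 7 lower calls with NRCWE-045 (3.94 and 0.439 for independent sets), and NRCWE-044 shared 68 and 8 (2.90 and 0.182). Both medians were 0 with split controls, and the highest values 22 and 24. Each split left 2 or 3 controls per comparison, which by itself lowers the calls. Leaving out control replicate 2 alone already gave 0 calls for NRCWE-045. The shared calls with split controls therefore cannot show how much of the overlap came from the shared controls. The covariance of log2 changes was 0.0403 for NRCWE-043 with NRCWE-044, 0.0282 for NRCWE-043 with NRCWE-045 and 0.0428 for NRCWE-044 with NRCWE-045. Simulations with shared controls and no effect gave 0.0133. Their genes and arrays varied independently, so this value does not bound what real arrays give. The same pairs at 18 µg lay below it, at 0.0023, -0.0035 and 0.0073. With split controls the medians at 54 µg were 0.0296, 0.0157 and 0.0285. Single splits ran from -0.0127 to 0.0540, -0.0200 to 0.0392 and 0.0158 to 0.0389.

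At 18 µg of NRCWE-043 Hmox1, which was also high in control replicate 7, was higher than in controls by 2.23 (SE 0.32, adjusted p = 8.8e-05), and a dimmer probe of the gene by 0.91. Ccl7 rose by 1.64 (SE 0.41, adjusted p = 0.015), the cytokine receptor Tnfrsf12a by 1.23, the immediate early gene Ier3 by 1.09 and the clock repressor Nr1d1 by 1.86, in all 5 arrays each. 6 of 20 cholesterol genes rose (7 adjusted over the list alone), with Idi1 at 0.60 and Hsd17b7 at 0.70; the mean change was 0.26 (95% interval 0.10 to 0.42, adjusted p = 6.7e-05, and adjusted p = 0.86 with an estimated correlation, all 5 arrays above the control mean, 0.02 to 0.31 within slides). CC chemokines (1 of 14 rose, 2 adjusted over the list alone; mean 0.52, adjusted p = 0.041, and adjusted p = 0.94 with an estimated correlation) and erythroid markers (1 of 6 fell, 1 adjusted over the list alone; mean -0.58, adjusted p = 0.02, and adjusted p = 0.94 with an estimated correlation) were the other lists called. The CC chemokine call was lost without control replicate 7, 15 or 30 or treated replicate 10 or 20 (adjusted p = 0.051 to 0.14) and with slide as a fixed block (adjusted p = 0.052). The erythroid call was lost without control replicate 30 (adjusted p = 0.070) or treated replicate 10 (adjusted p = 0.054). H2-Q4 was lower, at -2.07 (SE 0.32, adjusted p = 2.5e-04), with Slc26a1 at -1.94. Other probes of some called genes did not follow: nucleolin (Ncl) rose by 1.48, while its second probe was at 0.19, and the sialic acid transporter Slc17a5 fell by 1.59, while its second probe was at 0.13. Saa3 at 2.96 (adjusted p = 0.086), Timp1 at 1.55 (adjusted p = 0.12) and Ccl2 at 1.28 (adjusted p = 0.058) did not pass the test; without control replicate 29 all 3 were called (adjusted p = 0.014, 0.030 and 0.021).

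For NRCWE-043 at 18 µg limma called 1068 features, 344 higher and 724 lower (4889 at an unadjusted p under 0.05); 526 changed at least 1.5-fold. Of the called genes with another tested probe, 63 of 179 had one of opposite sign, against 41 of 345 for NRCWE-044 at 54 µg. The 830 features that set NRCWE-043 apart from the other materials, on which control replicate 7 scored 0.878, include Hmox1, H2-Q4, Slc26a1 and Nr1d1. The count was 1853 without control replicate 7 and 1925 without replicates 7 and 29, but 388 without control replicate 30, 567 without treated replicate 10, 584 without control replicate 2 and 650 without control replicate 15. With variance from these 10 arrays alone it was 0, with median centring 54 (13.0% higher against 32.2%) and with the clock score as a covariate 167, when the median change of the features called was 0.50 against 0.58 and its median SE 0.16 against 0.15. Ccl7 lost its call without treated replicate 10 (adjusted p = 0.066) or control replicate 15 or 30 (adjusted p = 0.056 and 0.062), and Nr1d1 without control replicate 2 or 30 (adjusted p = 0.056 and 0.069); without control replicates 7 and 29 Nr1d1 was at 2.99.

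At 18 µg NRCWE-044 and NRCWE-045 gave 0 calls in limma, with 2763 and 710 features at an unadjusted p under 0.05. Saa3 was at 1.33 (adjusted p = 0.61) and 1.59 (adjusted p = 1.00), and Cxcl5 at 1.44 (adjusted p = 0.41) and 1.25 (adjusted p = 1.00). Without control replicate 29 Saa3 was at 2.30 and 2.56, and without replicate 23 of NRCWE-044 at 0.39; Cxcl5 was at 0.62 without replicate 13 of NRCWE-045. Lists were called without single genes passing. With NRCWE-044, 11 of 17 T cell markers fell when adjusted over the list alone (mean -0.43, 95% interval -0.67 to -0.19, adjusted p = 5.8e-10, and adjusted p = 0.32 with an estimated correlation), below the control mean in all 5 arrays and by -0.52 to -0.26 within slides, with exact permutation p = 0.0079 (2-sided, adjusted 0.063). NK cell markers had a mean of -0.53 (adjusted p = 2.6e-05, and adjusted p = 0.54 with an estimated correlation) and B cell markers of -0.54 (adjusted p = 4.2e-04, and adjusted p = 0.69 with an estimated correlation); both calls were lost without control replicates 7 and 29 (adjusted p = 0.12 and 0.53). Heat shock genes had a mean of 0.38 (4 of 13 adjusted over the list alone; adjusted p = 6.2e-08, and adjusted p = 0.32 with an estimated correlation). Without control replicates 7 and 29 the mean was -0.21 for T cell markers and 0.19 for heat shock genes (both adjusted p = 0.0037). Markers of skeletal muscle had a mean of 1.24 (adjusted p = 7.7e-04, and adjusted p = 0.56 with an estimated correlation), carried by replicate 6, whose score was 5.14 against -0.83 to -0.32 in the other 4; without it the list was not called (mean 0.10, adjusted p = 0.44). The clock list, at -0.46 (adjusted p = 0.02, and adjusted p = 0.43 with an estimated correlation), lost its call without control replicate 7 (adjusted p = 0.067). Camera called 5 lists higher and 7 lower, 0 with an estimated correlation. With NRCWE-045 it called 6 higher and 3 lower, 0 with an estimated correlation, among them cholesterol genes (mean 0.17, 0.01 to 0.33, adjusted p = 5.9e-05, and adjusted p = 0.33 with an estimated correlation) and NF-kB targets (0.23, 0.04 to 0.42, adjusted p = 1.1e-04, and adjusted p = 0.33 with an estimated correlation), each above the control mean in all 5 arrays. The mean change of the members among NF-kB targets was 0.21, and 0.13 without replicate 13. Removing control replicate 30 gave 27 calls for NRCWE-044 and control replicate 2 gave 16; for NRCWE-045 leaving out any 1 array gave 0.

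**Figure D3:**
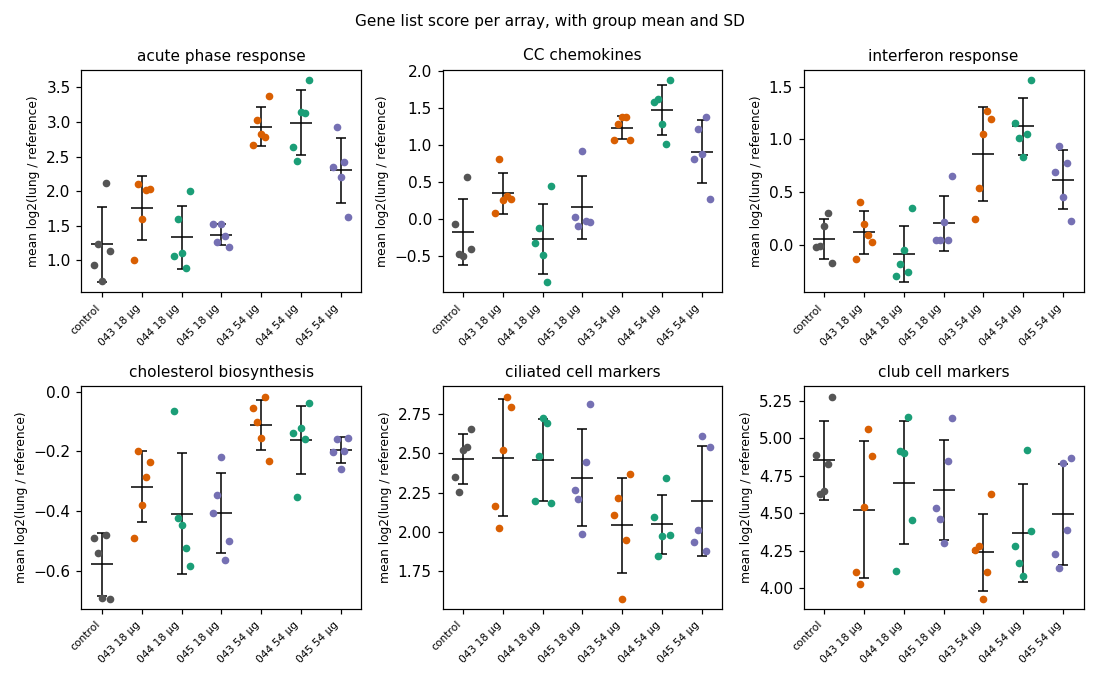
Mean log2 ratio of 6 gene lists on each array (points) in the 7 groups, with the group mean and SD (bars). The cholesterol list rose by 0.47, 0.42 and 0.38 over controls with NRCWE-043, NRCWE-044 and NRCWE-045 at 54 µg, with 95% intervals of 0.31 to 0.63, 0.26 to 0.58 and 0.22 to 0.54.

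The doses of each material were compared to ask what raising it from 18 to 54 µg changed. With NRCWE-044, Saa3 was 5.71 (SE 0.99, adjusted p = 4.1e-04) higher at 54 than at 18 µg, Saa1 3.98, Ccl24 3.58, Timp1 3.32 and Slc26a4 3.62. The aldehyde dehydrogenase Aldh3a1 fell by 1.87 (by 1.20 without 18 µg replicate 6, the array that stood apart for skeletal muscle markers) and Gsta2 by 1.76. 22 of 23 interferon-response genes rose (23 adjusted over the list alone; mean 1.22, 95% interval 0.85 to 1.58, adjusted p = 1.1e-30, and adjusted p = 0.017 with an estimated correlation), as did 10 of 14 CC chemokines (mean 1.74, 1.25 to 2.24, adjusted p = 3.3e-15, and adjusted p = 0.017 with an estimated correlation) and 9 of 15 acute phase genes (mean 1.66, 1.11 to 2.21, adjusted p = 3.5e-11, and adjusted p = 0.03 with an estimated correlation). With NRCWE-043, Saa1 rose by 3.22 (SE 0.59, adjusted p = 0.0083), Cxcl10 by 2.63, Orm2 by 2.35 and Saa3 by 3.84 (SE 0.99, adjusted p = 0.048). 7 of 15 acute phase genes (mean 1.18, 0.63 to 1.73, adjusted p = 4.9e-08, and adjusted p = 0.11 with an estimated correlation) and 7 of 23 interferon-response genes rose (mean 0.74, 0.37 to 1.11, adjusted p = 3.8e-17, and adjusted p = 0.11 with an estimated correlation). With NRCWE-045 limma called 0 features (975 at an unadjusted p under 0.05; 3 with variance from these arrays alone), the smallest p belonging to Serpina3m, Sdf2l1 and Ptger1 at 1.23, 0.92 and 0.62 (adjusted p = 0.96). Its acute phase list had a mean of 0.93 (0.39 to 1.48, adjusted p = 2.5e-14, and adjusted p = 0.025 with an estimated correlation; 9 of 15 adjusted over the list alone). For the acute phase each material was higher at 54 µg in all 5 arrays, with exact permutation p = 0.0079 (2-sided, 0.044 after adjustment), and within slides by 0.92 to 1.66, 1.32 to 1.70 and 0.83 to 1.41 for NRCWE-043, NRCWE-044 and NRCWE-045.

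Counts between the doses were 1664 for NRCWE-044 (1255 higher, 409 lower; 5097 at an unadjusted p under 0.05) and 295 for NRCWE-043 (234 higher, 61 lower; 3724 at an unadjusted p under 0.05). That of NRCWE-044 was 923 without its 54 µg replicate 34. That of NRCWE-043 was 7 without its 18 µg replicate 5, when Saa3 (adjusted p = 0.21), Saa1 and Cxcl10 (both adjusted p = 0.060) lost their calls. It was 45, 81, 136 and 149 without 54 µg replicates 19, 16, 22 and 9, when Saa3 lost its call too (adjusted p = 0.089 to 0.11). It was 448, 524 and 566 without 18 µg replicates 26, 20 and 33; Saa3 lost its call without replicate 26 (adjusted p = 0.051) and 20 (adjusted p = 0.075). Median centring moved the median of all genes by 0.13 for NRCWE-043 and 0.12 for NRCWE-045, and by -0.11 for the dose effect of NRCWE-044 minus that of NRCWE-043. It left 6 calls for NRCWE-043 and 83 for NRCWE-044, and made all of the former and 98.8% of the latter higher, against 79.3 and 75.4%. Without replicates 5, 6, 10 and 23, an alternative chosen after seeing the data, the calls were 75 higher and 97 lower for NRCWE-043 (43.6% higher) and 1523 higher and 1204 lower for NRCWE-044 (55.8% higher). Array weights gave 54.8 and 60.4% higher, so the excess of higher calls changed with the setting. The difference between dose effects was itself tested: 0 features were called for any pair of materials (836, 917 and 1143 at an unadjusted p under 0.05 for NRCWE-044 minus NRCWE-043, NRCWE-045 minus NRCWE-043 and NRCWE-045 minus NRCWE-044). In the last of these C1qtnf1 was at -0.74 (adjusted p = 0.13) and Cfb at -1.01 (adjusted p = 0.86); in the first Tnfsf13b was at 0.88 (adjusted p = 1.00), and in the second Mef2a at -0.63 (adjusted p = 1.00). Camera called 15 lists higher and 3 lower, 1 and 4, and 6 and 17, and 0 with an estimated correlation. For NRCWE-045 minus NRCWE-044 the interferon list had a mean of -0.82 (adjusted p = 1.2e-22, and adjusted p = 0.071 with an estimated correlation). In permutation tests of the list scores the smallest p of 156 was 5.0e-04, or 0.0786 after adjustment. Leaving out 1 array gave at most 1 call, for NRCWE-045 minus NRCWE-044 without 54 µg replicate 24 of NRCWE-044.

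The materials were compared at matched dose. At 54 µg the acute phase list of NRCWE-044 did not differ detectably from that of NRCWE-043 (difference 0.06, 95% interval -0.49 to 0.60, adjusted p = 0.64), nor did the CC chemokines (0.24, -0.25 to 0.73, adjusted p = 0.45). NRCWE-045 was below NRCWE-044 for interferon response (mean -0.51, -0.88 to -0.14, adjusted p = 1.1e-16, and adjusted p = 0.068 with an estimated correlation; 13 of 23 members lower when adjusted over the list alone), acute phase (-0.69, -1.23 to -0.14, adjusted p = 2.4e-07, and adjusted p = 0.097 with an estimated correlation) and the unfolded protein response (-0.28, -0.42 to -0.13, adjusted p = 8.4e-08, and adjusted p = 0.048 with an estimated correlation), in all 5 arrays each. The exact permutation p were 0.016, 0.048 and 0.024 (2-sided; 0.16, 0.28 and 0.19 after adjustment), and within slides the differences ran from -1.34 to -0.08, -1.99 to 0.50 and -0.64 to -0.02. No single feature passed limma between NRCWE-045 and NRCWE-044 at 54 µg (0 called, 1542 at an unadjusted p under 0.05, 33 with variance from these arrays alone, 12 without 54 µg replicate 14 of NRCWE-045 and 1 without replicate 31 of NRCWE-044); Ephx1, a hydrolase of epoxides, was at 0.76 (adjusted p = 0.054). NRCWE-045 was below NRCWE-043 for acute phase (mean -0.63, -1.18 to -0.08, adjusted p = 0.033, and adjusted p = 0.81 with an estimated correlation; 3 of 15 fell, 5 adjusted over the list alone; 4 of 5 arrays), with exact permutation p = 0.032 (2-sided, adjusted 0.22) and -0.31 to 0.13 within slides. For NRCWE-044 against NRCWE-043 the interferon list, at 0.27 (-0.10 to 0.64, adjusted p = 0.028, and adjusted p = 0.92 with an estimated correlation), turned to -0.07 with median centring, which moved the median of all genes by -0.17 in this comparison. Its call was lost without 54 µg replicate 3 of NRCWE-043 (adjusted p = 0.42) or 34 of NRCWE-044 (adjusted p = 0.21).

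Single genes separated NRCWE-043 from both other materials. Hmox1 was lower with NRCWE-044, at -3.00 (SE 0.32, adjusted p = 1.1e-07), and with NRCWE-045, at -3.23 (SE 0.32, adjusted p = 6.5e-08), at 54 µg. At 18 µg the differences were -2.33 (SE 0.32, adjusted p = 7.0e-06) and -2.69 (SE 0.32, adjusted p = 1.0e-06). H2-Q4 was higher by 2.97, 2.35, 3.00 and 2.67, in all 5 arrays each. These belong to the 830 features on which control replicate 7 also scored 0.878. On 167 other probes of such genes the median difference between NRCWE-044 and NRCWE-043 at 18 µg was 0.07, against 0.73 on the brightest. H2-Q4 was tested on 1 probe. No symbol was found for 60.1% of the 679 features lower and 31.1% of the 151 higher in NRCWE-043, against 38.8% of all tested. Dbp was lower with NRCWE-044 than with NRCWE-043, at -4.53 (SE 0.63, adjusted p = 9.4e-06) for 18 µg and -3.79 (SE 0.63, adjusted p = 8.1e-05) for 54 µg. Nr1d1 was at -3.72 and -2.94, and Arntl, the activator of the clock, higher by 2.43 at 18 µg. Clock score means were 2.02 and 1.58 for NRCWE-043 at 18 and 54 µg, -1.03 and -0.89 for NRCWE-044, 1.05 and 1.15 for NRCWE-045 and 0.84 ± 1.62 (SD, n = 5) for controls. Heat shock genes were higher with NRCWE-044 than with NRCWE-043 at 18 µg (8 of 13 rose, 9 adjusted over the list alone; mean 0.57, 0.32 to 0.83, adjusted p = 7.3e-07, and adjusted p = 0.49 with an estimated correlation). T cell markers were lower (8 of 17 fell; mean -0.48, -0.72 to -0.24, adjusted p = 4.7e-06, and adjusted p = 0.63 with an estimated correlation). Both held in all 5 arrays, with exact permutation p = 0.0079 (2-sided, adjusted 0.11) and within slides by 0.43 to 0.81 and -0.57 to -0.24. Between NRCWE-045 and NRCWE-044 at 18 µg the clock repressor Nr1d2 was higher by 2.36 (SE 0.38, adjusted p = 0.0019) and the tetraspanin Tspan4 by 1.83 (SE 0.21, adjusted p = 7.4e-06) with NRCWE-045. Arntl fell by 2.07.

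Limma called 2797 (1368 higher, 1429 lower) features for NRCWE-044 against NRCWE-043 at 18 µg, 2177 (1534 higher, 643 lower) for NRCWE-045 against NRCWE-043, and 115 (93 higher, 22 lower) for NRCWE-045 against NRCWE-044. At 54 µg the counts were 1940 (1390 higher, 550 lower), 1375 (992 higher, 383 lower) and 0. Of called genes with another tested probe, 138 of 496, 133 of 344, 82 of 243 and 79 of 179 had one of opposite sign in the comparisons with NRCWE-043 (NRCWE-044 and NRCWE-045 at 18 µg, then at 54 µg). With the clock score as a covariate, chosen after seeing the data, the counts of NRCWE-044 against NRCWE-043 were 0 at 18 µg and 36 at 54 µg. Those of NRCWE-045 against NRCWE-043 were 1243 and 1122, of which 1194 and 1110 features were called without it as well. The median change of the features called before went from 0.55 to 0.51 and from 0.61 to 0.58 for NRCWE-045. For NRCWE-044 at 54 µg it went from 0.60 (median SE 0.14) to 0.41 (median SE 0.20). NRCWE-045 against NRCWE-044 at 18 µg, where Nr1d2 and Arntl differed, fell from 115 calls to 1. Clock scores ran from -1.42 to -0.55 with NRCWE-044 and from 0.58 to 2.50 with the other 2 materials. The covariate therefore takes up part of any difference from NRCWE-044, whatever its cause. The lost calls cannot tell clock phase from material. Without 54 µg replicate 32 of NRCWE-045 the comparison with NRCWE-043 gave 908. For NRCWE-045 against NRCWE-044 at 18 µg the count was 37 without replicate 27, 42 without replicate 6, 51 without replicate 12, 64 without replicate 13, 69 without replicate 1 and 71 without replicate 25 or 23. Median centring gave 521, 375 and 0 at 18 µg and 851 and 529 at 54 µg. For NRCWE-044 against NRCWE-043 at 18 µg it made 77.4% of calls higher against 48.9%, and the Cy5 channel alone 37.8%. For NRCWE-045 against NRCWE-043 the Cy5 channel alone gave 60.0% and array weights 60.4% against 70.5%. For NRCWE-045 against NRCWE-044 at 18 µg, where 80.9% of the calls were higher, leaving out replicates 5, 6, 10 and 23 gave 33 higher and 28 lower (54.1%) and array weights 112 higher and 70 lower (61.5%). At 54 µg the clock covariate made 91.7% of the calls for NRCWE-044 against NRCWE-043 higher and the filter on all arrays 61.1%, against 71.6%.

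**Figure D4:**
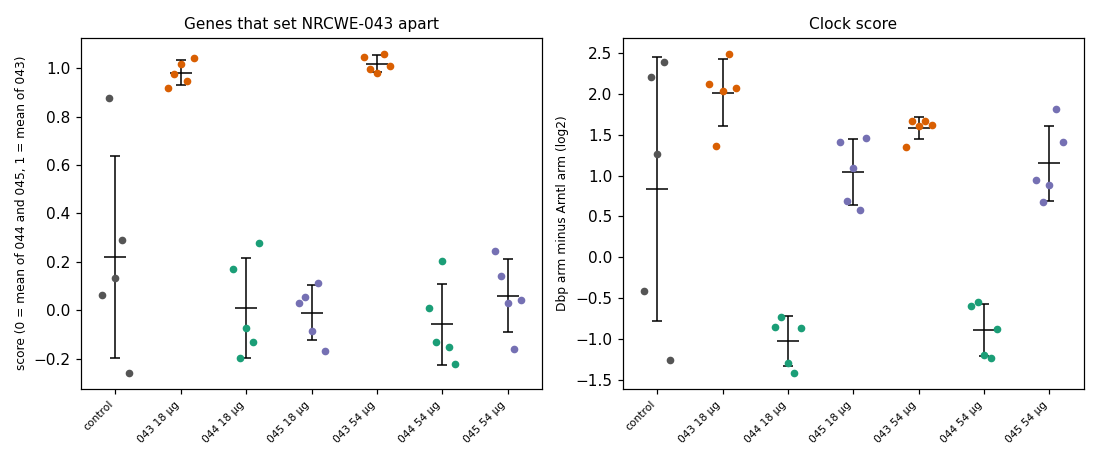
Left, mean score over 830 features on each array, scaled so that the other 2 materials average 0 and NRCWE-043 averages 1. The features were chosen on the treated arrays, so the separation of those arrays follows from the choice. Right, clock score in log2 units, genes that move with Dbp minus genes that move with Arntl. Points are arrays, and bars the group mean and SD; control replicate 7 lay at 0.878 on the left, and the controls ran from -1.27 to 2.40 on the right.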

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

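Arrays far from the other 4 of their group were sought with a Dixon test over 196 groups of 5 values (15 genes and 13 lists); it marked 16, where chance alone marks about 1 in 20. Among controls, replicate 29 stood apart for Saa3 (1.31, others -4.06 to -3.11), Ccl7 (-2.25, others -4.30 to -3.77), Timp1 (-0.22, others -3.03 to -2.49) and the CXC chemokine score (1.26, others 0.67 to 0.83), and replicate 30 for Cyp1a1 (2.31, others 0.25 to 0.74). With NRCWE-043 at 18 µg replicate 10 stood apart for Cxcl5 (-0.15, others -2.76 to -2.37), Ccl2 (-2.46, others -3.66 to -3.37) and Timp1 (1.36, others -1.37 to -0.79), and replicate 5 for the CXC chemokine score (0.61, others 1.09 to 1.18). At 54 µg replicate 16 of NRCWE-043 was low for Il1b (1.83, others 2.71 to 2.73), replicate 3 for Scgb1a1 (6.88, others 7.29 to 7.33), and replicate 31 of NRCWE-044 for Il6 (-1.65, others -0.94 to -0.70). With NRCWE-045 at 18 µg replicate 13 was high for CC chemokines (0.92, others -0.09 to 0.03) and replicate 27 for interferon response (0.65, others 0.04 to 0.22). With NRCWE-044 at 18 µg replicate 23 was low for the clock list (-0.15, others 0.15 to 0.20), and replicate 6 high for skeletal muscle markers (5.14, others -0.83 to -0.32).

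The test of the Cy3 channel was written before the values were seen, and the other tests of this pattern afterwards. The 830 features that separate NRCWE-043 from both other materials, with Hmox1 and H2-Q4 among them, were shifted in control replicate 7 as well. A difference in the reference channel might cause this, but Cy3 held 1.58% of the median difference, which argues against it. An effect of NRCWE-043 on the treated arrays is not excluded. With all labels right, it leaves unexplained the score of control replicate 7, 0.878 where NRCWE-043 averages 1, the observation that prompted the test. From 18 to 54 µg of NRCWE-043 these features moved by a median of 0.03. Their median absolute difference between NRCWE-044 and NRCWE-043 at 18 µg was 0.78. They were chosen for differing at both doses, which favours features without a dose trend, so this cannot decide on exposure. A wrong label of control replicate 7 is at odds with values below all 5 arrays of NRCWE-043 at 18 µg: its CC chemokine score by 0.556 (their SD 0.27), Saa3 at -3.73 (-1.38 to 2.61), Lcn2 at 1.97 (3.25 to 3.87), Ccl7 at -4.18 (-2.49 to -1.30), Ccl2 at -4.82 (-3.66 to -2.46), Timp1 at -2.76 (-1.37 to 1.36), Cxcl5 at -3.65 (-2.76 to -0.15) and Slc26a4 at 1.48 (3.70 to 5.88). It stays open, since Saa1 at 0.39, Il6 at -1.91 and Cxcl10 at -1.70 lay within the range of those arrays and its acute phase score 0.230 above the lowest; that score, 1.24 where the other controls averaged 1.23, includes Saa2 at 2.21, above them all, on the array with the highest hepatocyte marker score (1.66). On 167 other probes of these genes the median change was 0.07 against 0.73 on the brightest, with 58.7% of the same sign, against 89.2 and 89.8% for genes called with NRCWE-044 at 54 µg (against 18 µg and against control).

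The tests of the clock genes were chosen after the result was seen. Deviations from group means were taken for the 2 arms of the clock, genes that move with Dbp and genes that move with Arntl. They correlated at -0.798 over 35 arrays (permutation p = 1.0e-05, the smallest possible). The permutation exchanged deviations between groups of unlike spread, so its p is not exact. The Spearman correlation was -0.622, and the Pearson correlation without the 2 farthest arrays -0.685. Controls spread most, with a clock score SD of 1.62 against 0.135 to 0.460 in treated groups. The controls therefore weigh most in these correlations, which were not computed for the treated arrays alone and need not hold there. Lungs in different clock phases, as collection at different times of day gives, would show such opposite movement. Whether exposure could be the whole cause stays open. The single control arrays ranged over 1.20 of the largest difference between treated group means, but over 0.83 without replicates 7 and 29, whose labels are in question. A range of single arrays and a difference of means of 5 arrays are unlike measures, so this ratio cannot decide it. Collection times are not in the labels, so an effect of NRCWE-044 on the clock and a difference in collection time could both contribute. With the clock score as a covariate NRCWE-044 against NRCWE-043 fell from 2797 to 0 calls at 18 µg and from 1940 to 36 at 54 µg; the median change of the genes called before was 0.53 (SE 0.14) and became 0.32 (SE 0.22) at 18 µg. NRCWE-045 against NRCWE-044 at 18 µg fell from 115 calls to 1. Since the clock scores of NRCWE-044 did not overlap those of the other 2 materials, these losses cannot tell clock phase from material.

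The tests of control replicate 29 were chosen after the result was seen. Its acute phase score lay 1.12 above the mean of the other 4 controls, with Saa3 at 1.31. A batch effect of slide 5 might raise it. The NRCWE-045 array at 18 µg on that slide lay -0.339 from the highest of the other 4 of its group. At 1.19 it lay below their range of 1.27 to 1.53, while the outcome written for no batch effect was a value within that range. That array was thus not raised, but 1 array of another group cannot exclude an effect of the slide. A wrong label could account for the 1.12 and stays open; no biological explanation was tested.

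The 18 tests on other splits of the same arrays were written before the values were seen; each counted, among 100 splits, those, the real one included, that called at least as many features in limma as the real one. Against control the number was 3 for NRCWE-043 at 18 µg (real count 1068, highest other 1308), 100 for NRCWE-044 at 18 µg (real count 0, highest other 394) and 100 for NRCWE-045 at 18 µg (real count 0, highest other 4), and 1 for NRCWE-043 at 54 µg (real count 2606, highest other 1013), 1 for NRCWE-044 at 54 µg (real count 1518, highest other 260) and 1 for NRCWE-045 at 54 µg (real count 83, highest other 8). Between doses it was 1 for NRCWE-043 (real count 295, highest other 101), 1 for NRCWE-044 (real count 1664, highest other 1054) and 100 for NRCWE-045 (real count 0, highest other 6). At 18 µg it was 4 for NRCWE-044 against NRCWE-043 (real count 2797, highest other 6729), 1 for NRCWE-045 against NRCWE-043 (real count 2177, highest other 587) and 1 for NRCWE-045 against NRCWE-044 (real count 115, highest other 5). At 54 µg these materials gave 1 for NRCWE-044 against NRCWE-043 (real count 1940, highest other 330), 1 for NRCWE-045 against NRCWE-043 (real count 1375, highest other 1) and 100 for NRCWE-045 against NRCWE-044 (real count 0, highest other 15). For the dose effects it was 100 for NRCWE-044 minus NRCWE-043 (real count 0, highest other 1441), 100 for NRCWE-045 minus NRCWE-043 (real count 0, highest other 2) and 100 for NRCWE-045 minus NRCWE-044 (real count 0, highest other 669). For the 7 comparisons with a real count of 0 the number was 100 by construction and tests nothing. The split with 6729 calls, against 2797 in the real one, points to a structure of the samples that the groups do not describe. It set replicates 5 and 10 of NRCWE-043 and 6, 11 and 23 of NRCWE-044 apart from the others. Of these, replicates 5, 6, 10 and 11 lay on slides 1 and 2, scanned on day 1, and the others on slides 3, 4 and 7. Replicate 23, on slide 4, had the highest median Cy5 signal of all arrays (345.5) and 1115 marked spots. Slide, scan day and signal were not tested as causes of this split. For NRCWE-043 at 18 µg the 1308 came from exchanging control replicate 7 with treated replicate 20.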

How the results depend on the processing

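Of 998 named gene results, 18748 values under alternatives other than leaving out 1 array gave the same direction and side of the threshold in 17603 cases, a weaker result in 736, a stronger in 404 and a reversed sign in 5. Of those the same, 998 came from quantile normalization of average intensities, which by construction leaves the log2 ratios unchanged. Leaving out 1 array gave 9838 of 10520 the same, 570 weaker and 112 stronger. Median centring weakened 246 of the 998, and the filter on all arrays kept 784, since fewer probes were tested. Of 263 list calls an estimated correlation kept 24, a rotation test (fry) 99, slide as a block 216, Feature Extraction signals 217, no filter 260 and the set without control replicates 7 and 29 244. Of 3090 list results with 1 array left out, 2727 were the same, 361 weaker and 2 reversed. Under other scalings the list means turned from -0.28 to 0.16 (Feature Extraction signals) and 0.10 (scale normalization) for club cell markers between the doses of NRCWE-043, where scale normalization turned cell cycle genes from 0.23 to -0.0018, and from 0.25 to -0.07 (scale normalization) for endothelial markers in NRCWE-045 against NRCWE-043 at 54 µg. The Cy5 channel alone turned Scgb1a1 in NRCWE-044 against NRCWE-043 at 54 µg to -0.0082. The clock covariate turned Arntl and Dbp in NRCWE-044 against NRCWE-043 at 18 µg to -0.32 and 0.0010, and Dbp and Cdkn1a in NRCWE-045 against NRCWE-044 at 18 µg to -0.26 and 0.0067; by construction it removes what follows the clock genes. Without replicate 6 of NRCWE-044 at 18 µg the skeletal muscle list turned to 0.018 for the dose effect of NRCWE-044 minus that of NRCWE-043 and to -0.046 for NRCWE-045 minus NRCWE-044; with each array left out in turn these ran from -1.47 to 0.018 and from -0.046 to 1.45. Slide as a random block had a correlation of 0.185, and array weights ran from 0.236 to 1.97. On the array with the fewest, 42.8% of probes lay well above background, so the other probes were measured near background there. How far signal limits the counts was not tested by itself: the filter on all arrays raised some (83 to 129) and lowered others (1940 to 1077).

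Counts of features called that moved are given by setting, and a treated group named alone stands for its comparison with control; where the setting does not by itself reduce the arrays, probes or calls, the cause was not tested. Median centring gave 54 for NRCWE-043 at 18 µg, 524 for NRCWE-043 at 54 µg, 43 for NRCWE-044 at 54 µg, 0 for NRCWE-045 at 54 µg and 6 for NRCWE-043 between doses. The other counts were 83 for NRCWE-044 between doses, 521 for NRCWE-044 against NRCWE-043 at 18 µg, 375 for NRCWE-045 against NRCWE-043 at 18 µg, 0 for NRCWE-045 against NRCWE-044 at 18 µg and 851 for NRCWE-044 against NRCWE-043 at 54 µg. Further counts were 529 for NRCWE-045 against NRCWE-043 at 54 µg. The Cy5 channel alone gave 710 for NRCWE-043 at 18 µg, 1 for NRCWE-044 at 18 µg, 31 for NRCWE-045 at 54 µg, 752 for NRCWE-043 between doses and 230 for NRCWE-045 against NRCWE-044 at 18 µg. It also gave 3 for NRCWE-045 against NRCWE-044 at 54 µg. Feature Extraction processed signals gave 207 for NRCWE-045 at 54 µg, 33 for NRCWE-043 between doses, 247 for NRCWE-045 against NRCWE-044 at 18 µg and 8 for NRCWE-045 against NRCWE-044 at 54 µg. The deposited value table gave 8 for NRCWE-045 against NRCWE-044 at 54 µg and 1 for the dose effect of NRCWE-045 minus that of NRCWE-044. No background correction gave 5 for NRCWE-045 against NRCWE-044 at 54 µg. Scale normalization gave 50 for NRCWE-045 at 54 µg. The filter on all arrays gave 129 for NRCWE-045 at 54 µg, 1077 for NRCWE-044 against NRCWE-043 at 54 µg, 819 for NRCWE-045 against NRCWE-043 at 54 µg and 7 for NRCWE-045 against NRCWE-044 at 54 µg. The mean over the probes of a gene gave 1 for NRCWE-045 against NRCWE-044 at 54 µg. Slide as a fixed block gave 1608 for NRCWE-043 at 18 µg, 2291 for NRCWE-044 at 54 µg, 158 for NRCWE-045 at 54 µg, 679 for NRCWE-043 between doses and 3495 for NRCWE-045 against NRCWE-043 at 18 µg. The other counts were 5 for NRCWE-045 against NRCWE-044 at 54 µg. Slide as a random block gave 1812 for NRCWE-043 at 18 µg, 2305 for NRCWE-044 at 54 µg, 273 for NRCWE-045 at 54 µg, 699 for NRCWE-043 between doses and 3305 for NRCWE-045 against NRCWE-043 at 18 µg. Further counts were 293 for NRCWE-045 against NRCWE-044 at 18 µg, 17 for NRCWE-045 against NRCWE-044 at 54 µg and 1 for the dose effect of NRCWE-045 minus that of NRCWE-044. Variance from only the groups compared gave 0 for NRCWE-043 at 18 µg, 32 for NRCWE-045 at 54 µg, 28 for NRCWE-043 between doses, 717 for NRCWE-044 between doses and 3 for NRCWE-045 between doses. It also gave 1220 for NRCWE-044 against NRCWE-043 at 18 µg, 43 for NRCWE-045 against NRCWE-044 at 18 µg and 33 for NRCWE-045 against NRCWE-044 at 54 µg. Array weights gave 2328 for NRCWE-044 at 54 µg, 348 for NRCWE-045 at 54 µg, 655 for NRCWE-043 between doses, 2701 for NRCWE-044 between doses and 182 for NRCWE-045 against NRCWE-044 at 18 µg. The other counts were 2098 for NRCWE-045 against NRCWE-043 at 54 µg, 63 for NRCWE-045 against NRCWE-044 at 54 µg and 1 for the dose effect of NRCWE-045 minus that of NRCWE-044. Leaving out control replicates 7 and 29 gave 1925 for NRCWE-043 at 18 µg, 1 for NRCWE-045 at 18 µg, 880 for NRCWE-044 at 54 µg, 177 for NRCWE-045 against NRCWE-044 at 18 µg and 17 for NRCWE-045 against NRCWE-044 at 54 µg. Leaving out replicates 5, 6, 10 and 23 gave 3955 for NRCWE-043 at 54 µg, 2791 for NRCWE-044 at 54 µg, 471 for NRCWE-045 at 54 µg, 172 for NRCWE-043 between doses and 2727 for NRCWE-044 between doses. Further counts were 61 for NRCWE-045 against NRCWE-044 at 18 µg and 53 for NRCWE-045 against NRCWE-044 at 54 µg. The clock score as a covariate gave 167 for NRCWE-043 at 18 µg, 1 for NRCWE-045 at 18 µg, 1559 for NRCWE-043 at 54 µg, 746 for NRCWE-044 at 54 µg and 0 for NRCWE-044 against NRCWE-043 at 18 µg. It also gave 1243 for NRCWE-045 against NRCWE-043 at 18 µg, 1 for NRCWE-045 against NRCWE-044 at 18 µg and 36 for NRCWE-044 against NRCWE-043 at 54 µg. A fold change of at least 1.5 gave 526 for NRCWE-043 at 18 µg, 1180 for NRCWE-043 at 54 µg, 695 for NRCWE-044 at 54 µg, 50 for NRCWE-045 at 54 µg and 192 for NRCWE-043 between doses. The other counts were 807 for NRCWE-044 between doses, 1127 for NRCWE-044 against NRCWE-043 at 18 µg, 962 for NRCWE-045 against NRCWE-043 at 18 µg, 1022 for NRCWE-044 against NRCWE-043 at 54 µg and 748 for NRCWE-045 against NRCWE-043 at 54 µg. Further counts were 315 for calls higher with both NRCWE-043 and NRCWE-044, 40 for calls higher with both NRCWE-043 and NRCWE-045 and 41 for calls higher with both NRCWE-044 and NRCWE-045. Splitting the controls into 2 and 3 gave 164.5 for calls higher with both NRCWE-043 and NRCWE-044, 0 for calls higher with both NRCWE-043 and NRCWE-045 and 0 for calls higher with both NRCWE-044 and NRCWE-045.

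With each array left out in turn the counts ran from 388 to 1853 for NRCWE-043 at 18 µg, 0 to 27 for NRCWE-044 at 18 µg, 0 to 0 for NRCWE-045 at 18 µg, 1441 to 3092 for NRCWE-043 at 54 µg, 752 to 1790 for NRCWE-044 at 54 µg and 0 to 221 for NRCWE-045 at 54 µg. Between doses and materials they ran from 7 to 566 for NRCWE-043 between doses, 923 to 2057 for NRCWE-044 between doses, 0 to 0 for NRCWE-045 between doses, 2041 to 2909 for NRCWE-044 against NRCWE-043 at 18 µg, 1465 to 2466 for NRCWE-045 against NRCWE-043 at 18 µg and 37 to 159 for NRCWE-045 against NRCWE-044 at 18 µg. The remaining ranges were 1454 to 1863 for NRCWE-044 against NRCWE-043 at 54 µg, 908 to 1364 for NRCWE-045 against NRCWE-043 at 54 µg, 0 to 12 for NRCWE-045 against NRCWE-044 at 54 µg, 0 to 0 for the dose effect of NRCWE-044 minus that of NRCWE-043, 0 to 0 for the dose effect of NRCWE-045 minus that of NRCWE-043 and 0 to 1 for the dose effect of NRCWE-045 minus that of NRCWE-044.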

Other observations

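The genes named here were chosen after their values were seen, from those called with all 3 materials at 54 µg; values are log2 changes in the order of the code numbers of the materials. Ch25h, which makes 25-hydroxycholesterol, rose by 1.34, 1.40 and 1.36. The subunits of the replicative helicase Mcm3, Mcm5 and Mcm6 rose by 1.29, 1.23 and 0.87, by 1.02, 1.11 and 0.73 and by 0.97, 1.00 and 0.83. Il18bp, which binds and blocks interleukin 18, rose by 1.18, 1.20 and 1.03, and Csf2rb, the shared receptor chain for GM-CSF, by 0.76, 0.78 and 0.70. The transferrin receptor Tfrc rose by 0.61, 0.61 and 0.52, and Lgals1, a galectin, by 0.97, 1.18 and 0.92. The transporter Slc16a11 was lower, at -0.95, -1.20 and -0.88, as was the mitochondrial protein gene Bnip3, at -0.47, -0.43 and -0.60.

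The arrays differed in brightness within groups: replicate 23 of NRCWE-044 at 18 µg had a median Cy5 signal of 345.5 and replicate 24 of NRCWE-044 at 54 µg one of 230.0. The first 2 principal components held 22.5 and 16.1% of the variance. On the second, replicates 5 and 10 of NRCWE-043 at 18 µg scored 51.4 and 31.1. Replicates 6 and 23 of NRCWE-044 at 18 µg scored 68.9 and 31.1, and every other array 17.8 or less. These 4 arrays, left out together in 1 alternative, also had the lowest array weights (0.236, 0.325, 0.265 and 0.252 in that order).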
